A study of Mus musculus with 96 samples.

How the data were processed

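The data are RNA-seq libraries of 96 single cells of mouse bone marrow, each cell given as 1 GEO sample. Per the labels' protocols, cells were sorted as CD11b positive, Ly6G negative, CD115 positive, F4/80 negative and Ly6C high, separated on a Fluidigm C1 microfluidic system, amplified with SMARTer chemistry, made into Nextera XT libraries and sequenced as read pairs. The labels place 80 cells in a Ly6Chi sort and 16 in a sort that was also high for Gfi1 and Irf8. The Ly6Chi cells came from 2 captures of 25 January, chip 170 with 42 cells and chip 320 with 38. The Gfi1hi Irf8hi cells are labelled 27 January without a chip number, and were treated as 1 capture. Sort, capture and date therefore cannot be told apart. The genotype label is wild-type for every cell, while the protocol also names reporter mice, and nothing ties cells to animals. Mouse strain may therefore differ between the sorts too. Another label calls the differentiation in vitro, whereas the protocol describes cells taken from marrow, which was followed here.

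The deposited values are TPM, a measure of relative transcript abundance, made by the authors with RSEM on mm9, per the submitters' processing notes. The aligner, the annotation and the versions are not given in the sources used here. Each column summed to 1000000, so TPM kept no depth and the number of reads per cell is unknown. The table listed 23955 genes, of which 11497 were at 0 in every cell and 12458 above 0 in some cell. A value of 0 is described as listed at 0, because broadly used genes were also at 0 in some cells. No mitochondrially encoded gene and no spike-in was listed, so neither could serve as a measure of cell quality. Gene symbols are those of the table. No coordinates are given, because the reference genome at hand was of another build.

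Levels were means over cells of log2(TPM + 1), with the SD over cells as a description. A difference is Gfi1hi Irf8hi minus Ly6Chi, on this scale, which understates the difference of low genes. It was also taken against each chip and set beside chip 170 minus chip 320, which shows what a capture alone gave. The labels name no animal or culture, so each sort is 1 sample. Cells are not replicates, and no test, p-value or count of changed genes was made. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. Where a share was 0, the limit given in its place is 3 counts of the total, which bounds cells with a listed value and not cells that express the gene.

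Before the data were examined, 25 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. They were the lists of sort markers, primary granule, secondary and tertiary granule, MHC class II, dendritic cell, Ly6Clo monocyte, tissue macrophage, S phase, G2/M phase, interferon response, immediate early, inflammatory response, progenitor, ribosomal protein, mitochondrial respiratory chain, glycolysis, myeloid transcription factor, 7 lists of other cell types and a sex-linked list. A list's value was the median difference of its members. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries. The named genes were the 12 highest and 12 lowest between the sorts, ranked by the smaller of the differences against the 2 chips. They had to share a sign, exceed the difference between the chips and reach 1 TPM in at least 50% of cells of the higher sort. For the primary granule and MHC class II scores, the 10 genes with the highest and the 6 with the lowest correlation in both chips were named. List members of the highest level are named as examples, and so are the genes of the sort. Serpinb1a, Ms4a3, H2-Aa, H2-DMb1, Ctsg with Fcnb, Hba-a1, Kit and Cd34 were named after their values were seen.

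Co-expression was the mean pairwise Spearman correlation of members at 1 TPM or more in at least 10% of the Ly6Chi cells, computed within each chip and averaged, so that a difference between the chips added nothing. A score was the mean log2(TPM + 1) of a list's members per cell. Gfi1hi Irf8hi cells were held out of these choices. A cell was to be set aside as holding another cell type where 3 or more markers of 1 of the 7 lists of other cell types reached 10 TPM. No cell did. None of these lists covers neutrophils, so the check could not flag one. Cell 39 of chip 170, which was kept, had S100a8 as its highest gene. Its secondary and tertiary granule score was 10.57, against a Ly6Chi mean of 2.53 ± 1.33 (SD over 80 cells). No cell had fewer than 1000 genes at 1 TPM or more, so all 96 were used. Doublets were not called, since the files hold no counts.

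The alternatives changed the pseudocount to 0.1 or 10, the average, the scaling, the cells, the chip and the correlation. The scaling alternative used the median of 285 genes at 1 TPM or more in at least 90% of cells. Others were added after the data were seen, namely leaving out shallow cells, leaving out the 3 Gfi1hi Irf8hi cells with Hba-a1 or Hbb-b1 at 10 TPM or more, and matching cells on the number of genes. A cell counted as shallow where the 1st percentile of its values above 0 was 0.5 TPM or more. Matching took for each Gfi1hi Irf8hi cell the nearest unused Ly6Chi cell within 300 genes. It left out 4 Gfi1hi Irf8hi cells and kept the shallow ones, so matched values reflect this choice of cells as well as gene number. A ribosomal protein score of 7 was chosen, also after the data were seen, to count cells of low ribosomal transcript levels. The scripts were tested on simulated data with 6554 genes, drawn gene by gene from Ly6Chi values, so with no relation between genes. For planted differences of 2 the median found was 1.78 and 100% of those genes had the right sign, and for -2 they were -1.95 and 98%. Of 100 simulated lists without a difference, 4% lay above the 97.5th percentile. Members of several real lists were correlated, so this rate need not hold for them. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.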

Results

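Transcript levels were measured in 96 single monocytes of mouse bone marrow, 80 from a Ly6Chi sort and 16 from a sort of Ly6Chi cells high for the transcription factors Gfi1 and Irf8. The series addresses heterogeneity among Ly6Chi monocytes made by 2 kinds of progenitor, granulocyte-monocyte and monocyte-dendritic cell progenitors. Read depth is unknown because the values are TPM. The number of genes at 1 TPM or more had a median of 2019.5 per Ly6Chi cell, with a range of 1310 to 4310. It was 2196 on chip 170, 1924.5 on chip 320 and 3480 in Gfi1hi Irf8hi cells, whose range was 2119 to 4878. The median difference of all 12458 detected genes was 0.26 on the log2 scale, and that of the 1361 genes found in most cells was 0.67. List differences are therefore set beside the median of random lists of matched expression. Rescaling each cell moved the median of those 1361 genes to 0.87. Cells counted as shallow, whose smallest listed values were high, numbered 4 of 16 Gfi1hi Irf8hi and 4 of 80 Ly6Chi cells. The ribosomal protein score, a mean log2 level, lay between 3.71 and 6.82 in 5 of 16 Gfi1hi Irf8hi cells, 4 of them shallow, and between 9.91 and 10.99 in the other 11. It was below 7 in 5 of 80 Ly6Chi cells.

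The genes of the sort were measured first, because they check the labels. Irf8, a transcription factor of monocytes and dendritic cells, had a mean of 5.80 ± 3.33 (SD over 16 cells) in Gfi1hi Irf8hi cells and 4.11 ± 3.64 (SD over 80 cells) in Ly6Chi cells. The difference was 1.69, or 1.23 against chip 170 and 2.21 against chip 320. In cells matched on the number of genes it was -1.45, but 2.46 without shallow cells and 2.41 without the cells holding haemoglobin transcripts. Gfi1 was listed at 0 in all 16 Gfi1hi Irf8hi cells, where 3 counts of the total allow a share of up to 18.75% of cells with a listed value, and above 0 in 1 Ly6Chi cell, at 27.4 TPM. The Gfi1 transcript thus gave no check of the label. The labels do not say which mice, wild-type or reporter, gave these cells. A sort for high Gfi1 and Irf8 would need the reporter mice that the protocol names, so mouse strain may differ between the sorts. Ly6c2, which encodes the sorted surface antigen, reached 1 TPM in all 80 and all 16 cells, with means of 10.98 ± 2.89 and 11.64 ± 2.29. Ly6c1 had means of 4.29 ± 2.39 and 5.06 ± 2.82. In matched cells both were lower in Gfi1hi Irf8hi cells, with differences of -1.11 for Ly6c2 and -1.39 for Ly6c1. Csf1r, the receptor known as CD115, had means of 5.39 ± 4.04 and 4.0 ± 2.63, with a difference of 0.14 in matched cells, and Itgam, which encodes CD11b, 4.04 ± 3.56 and 1.19 ± 2.42. Emr1, the gene of F4/80, had means of 3.10 ± 3.77 and 2.10 ± 2.90, and differed by 0.24 in matched cells. The median of the 11 sort markers measured was lower by value in Gfi1hi Irf8hi cells (difference -1.40, median of random lists 0.78). It was -0.51 without the shallow cells, -0.77 in matched cells, -0.27 with medians over cells and -2.41 with the ratio of means.

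Gfi1hi Irf8hi cells had higher levels of cell division transcripts than Ly6Chi cells did, and of primary granule transcripts when all cells were compared. Every one of the 20 S phase and 20 G2/M phase genes was higher than on both chips. The median difference was 3.47 for S phase genes, with 0.99 for random lists, and 3.36 for G2/M genes, with 1.10 for random lists. Both lay at percentile 100. The 2 chips of the Ly6Chi sort also stood apart, by -0.46 for S phase (percentile 0.01) and -0.44 for G2/M genes (0.05), chip 170 minus chip 320. For primary granule genes the median difference between the sorts was 2.35, with 0.61 for random lists and percentile 100, and 8 of 11 members were higher than on both chips, which differed by -0.19. In 12 pairs of cells matched on the number of genes, the direction of the granule list turned, with a median of -1.16 (percentile 3.87, random lists -0.27), 4 members higher and 7 lower. The match left out the Gfi1hi Irf8hi cells with the highest granule scores (8.58, 5.68 and 5.68) and kept the shallow ones.

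**Figure D1:**
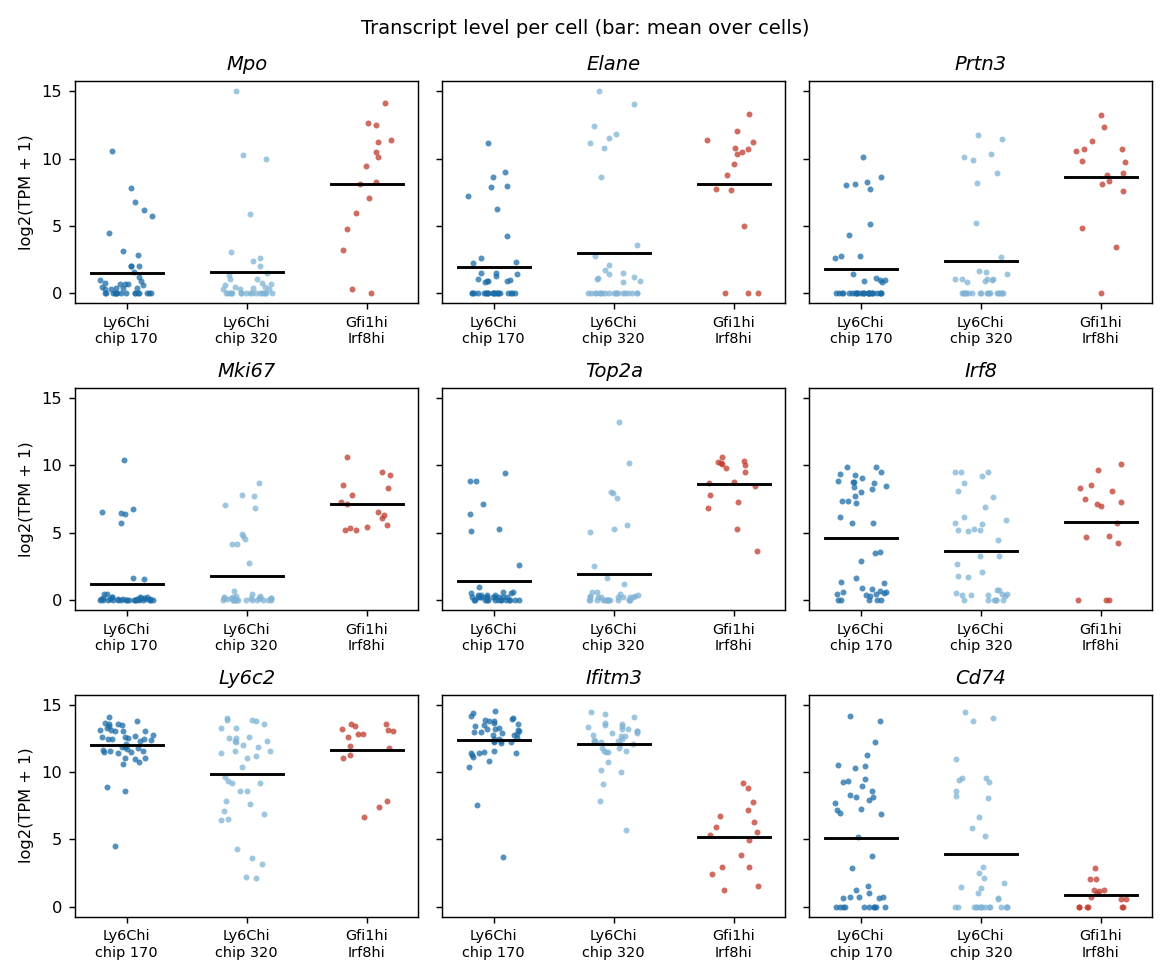
Levels of 9 genes in each cell, as log2(TPM + 1) on the vertical axis, by sort and capture, with the mean over cells as a bar. Mki67 and Top2a lie above 10 TPM in all 16 Gfi1hi Irf8hi cells, and Ifitm3 has a mean of 5.17 there against 12.27 in Ly6Chi cells.

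Among the cycle genes, Top2a, a DNA topoisomerase of dividing cells, had means of 8.58 ± 2.00 in Gfi1hi Irf8hi and 1.66 ± 3.06 in Ly6Chi cells. The proliferation marker Mki67 had 7.12 ± 1.71 and 1.43 ± 2.65. Both reached 10 TPM in 16 of 16 Gfi1hi Irf8hi cells (100%, exact 95% interval 79.4% to 100%), and Mki67 did so in 16 of 80 Ly6Chi cells (20%, 11.9% to 30.4%). Rrm2, a subunit of ribonucleotide reductase, differed by 6.86, the survivin gene Birc5 by 5.82 and the mitotic motor gene Kif11 by 5.51. Other genes among the 12 highest were 2810417H13Rik (6.23), Asf1b (5.85), Smc4 (5.38), Stmn1 (6.13) and Hmgn2 (6.43). In cells matched on the number of genes the G2/M median was 1.15 (percentile 99.97) and the S phase median 0.90 (99.82), with 15 of 20 members of each list higher and 5 lower. The lower ones included Cdk1 (-1.43), Ccnb2 (-1.34), Mcm4 (-0.88) and Hmmr (-0.76). Stmn1 differed by 0.16 there and Hmgn2 by 1.18.

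Among the primary granule genes, Mpo, the gene of myeloperoxidase, had means of 8.09 ± 4.28 and 1.55 ± 2.88, a difference of 6.54. Prtn3, which encodes proteinase 3, had 8.65 ± 3.42 and 2.06 ± 3.45, and Elane, which encodes neutrophil elastase, 8.07 ± 4.45 and 2.43 ± 4.02. Mpo reached 1 TPM in 14 of 16 Gfi1hi Irf8hi cells (87.5%, 61.7% to 98.4%) and 25 of 80 Ly6Chi cells (31.2%, 21.4% to 42.6%). For Prtn3 the shares were 93.8% (69.8% to 99.8%) and 36.2% (25.8% to 47.8%), for Elane 81.2% (54.4% to 96.0%) and 41.2% (30.4% to 52.8%), and for Ctsg, the gene of cathepsin G, 50% (24.7% to 75.3%) and 13.8% (7.07% to 23.3%). In the matched cells, Mpo stayed higher by 3.51, Prtn3 by 1.90 and Elane by 0.83, while Ctsg (-3.53), Ms4a3 (-1.16) and Serpinb1a (-4.97) were lower. Hba-a1, a haemoglobin gene and a mark of red cell RNA, reached 1 TPM in 4 Gfi1hi Irf8hi cells and 0 Ly6Chi cells. Without the 3 Gfi1hi Irf8hi cells holding Hba-a1 or Hbb-b1 at 10 TPM or more, the granule median was 2.90.

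Interferon response genes were lower by value in Gfi1hi Irf8hi cells. Of 20 such genes 18 were lower than on both chips, with a median of -0.90 (random lists 0.42, percentile 0.00), where the chips differed by 0.24 (percentile 99.01). In matched cells the median of the 20 was -0.33, with 14 lower and 2 higher. The list's value was 0 with medians over cells and -4.24 with the ratio of means. Xaf1 differed by -1.11, Irf7 by -2.81 and Rtp4 by -3.12, but by 0.0858 in matched cells. The 12 lowest genes lay outside this list. Among them Ifitm3, an interferon-induced membrane protein gene, had means of 5.17 ± 2.48 and 12.27 ± 1.81, and Ifi27l2a 1.69 ± 2.21 and 8.90 ± 3.96. Wfdc17 differed by -7.14, the chemokine gene Ccl6 by -6.30, the lysosomal membrane gene Cd68 by -5.00 and the apolipoprotein gene Apoe by -4.94. The others were Clec4a3 (-4.83), LOC100038947 (-4.72), Clec4a1 (-4.51), Evi2a (-3.99), Cd177 (-3.63) and Susd3 (-3.31). In matched cells all 12 stayed lower, from -5.78 for Ifitm3 and -3.67 for Cd68 to -1.91 for Apoe, -1.49 for Clec4a1, -1.27 for Clec4a3 and -0.98 for LOC100038947.

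MHC class II genes, which serve antigen presentation, had a median difference of -0.61 (random lists 0.55, percentile 0.01). Of 9 members, 5 were lower and 2 higher than on both chips. Cd74, the invariant chain, had means of 0.86 ± 0.90 and 4.55 ± 4.71, and H2-Aa 0.36 ± 1.25 and 1.53 ± 3.52. Ifi30, the member of the highest level, differed by 0.34. H2-DMb1 was higher in Gfi1hi Irf8hi cells under every setting run, by 0.65 to 4.73. Without the shallow cells the median was -0.052, and without the 3 cells holding haemoglobin transcripts -0.20. In matched cells it was -0.64, inside the random lists (percentile 5.49). Dendritic cell genes had a median of -0.15 (random lists 0.17, percentile 0.11), with Id2 at -2.44 and Cd209a at -0.87. In matched cells the list lay inside the random lists (percentile 8.33), and Id2 turned to 0.40. Secondary and tertiary granule genes had a median of -0.10 (random lists 0.39, percentile 0.61), with 4 of 16 higher and 6 lower than on both chips. The median was -0.13 against chip 170 and -0.024 against chip 320, and in matched cells it lay inside the random lists (percentile 6.40). Of these, Chil3 differed by -1.93 and the haptoglobin gene Hp by -0.55.

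**Figure D2:**
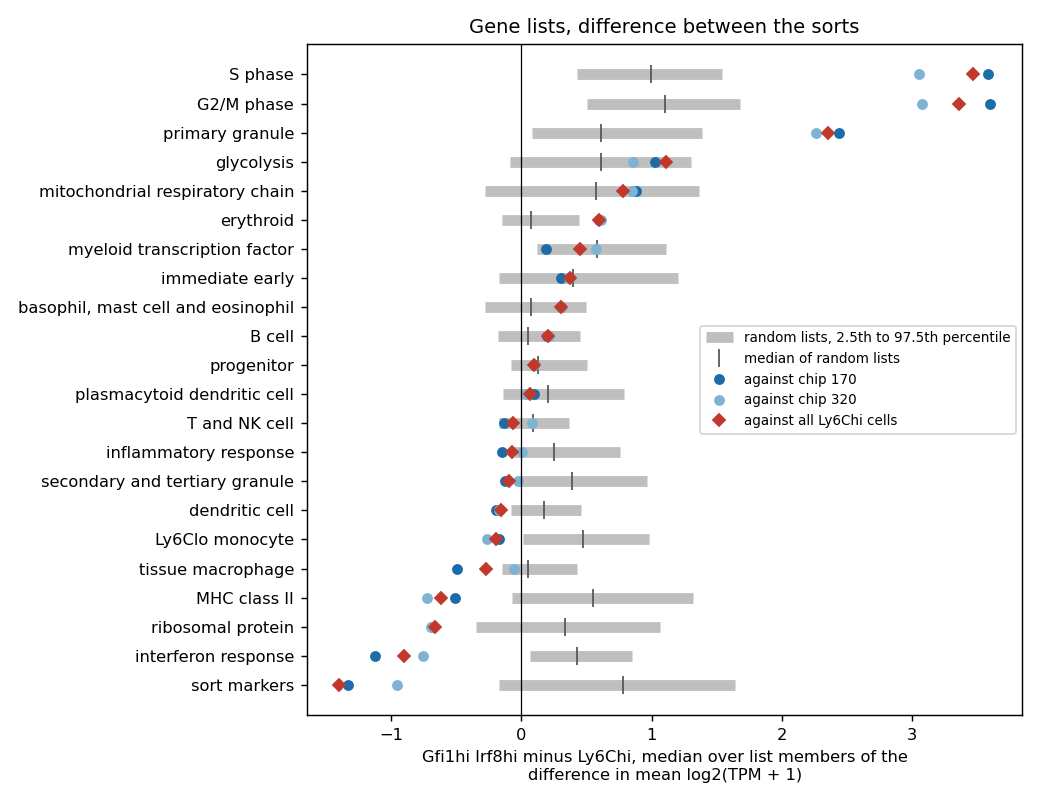
Median difference between the sorts for each gene list with 3 or more members above 0, on the log2(TPM + 1) scale, against all Ly6Chi cells and against each chip, with random lists as grey bars. S phase (3.47), G2/M phase (3.36) and primary granule (2.35) lie to the right of their random lists, and interferon response (-0.90) and sort markers (-1.40) to the left.

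Within the Ly6Chi sort, the question was whether granule and antigen presentation programmes varied from cell to cell as units. Primary granule transcripts had a mean pairwise correlation of 0.377 (random lists 0.042, percentile 100). It was 0.277 on chip 170 and 0.477 on chip 320, and 0.318 in the held-out Gfi1hi Irf8hi cells (percentile 99.83). Ctsg with Ms4a3 had 0.60, Ctsg with Fcnb 0.57 and Elane with Ctsg 0.52. Without the Ly6Chi cells holding Mki67, Top2a or Cdk1 at 10 TPM the list's value was 0.120, when that of MHC class II genes was 0.139. S phase genes had 0.273 and G2/M genes 0.286, both at percentile 100, and 0.065 and 0.055 without those cells.

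MHC class II genes had a mean correlation of 0.164 (percentile 99.82), carried by H2-Aa with Cd74 (0.53), H2-Aa with H2-Ab1 (0.52) and H2-Ab1 with Cd74 (0.42). Ifi30 with H2-Aa had -0.12. In Gfi1hi Irf8hi cells the list had 0.215, at percentile 79.6. Secondary and tertiary granule genes had 0.109 (percentile 99.97), but 0.058 (percentile 34.95) in Gfi1hi Irf8hi cells. Dendritic cell genes had 0.016 (percentile 33.82), within random lists.

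The primary granule and MHC class II scores were nearly unrelated across Ly6Chi cells. The Spearman correlation was 0.072, with 0.069 on chip 170 and 0.075 on chip 320, and 0.071 without the 2 farthest cells. Random pairs of lists had a median of 0.242, and the value lay at their percentile 7.26. The Pearson correlation was -0.07, or -0.01 without the 2 farthest cells. The Pearson correlation, the partial correlation and the exclusion of cycling cells moved this value by more than the difference between the chips.

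**Figure D3:**
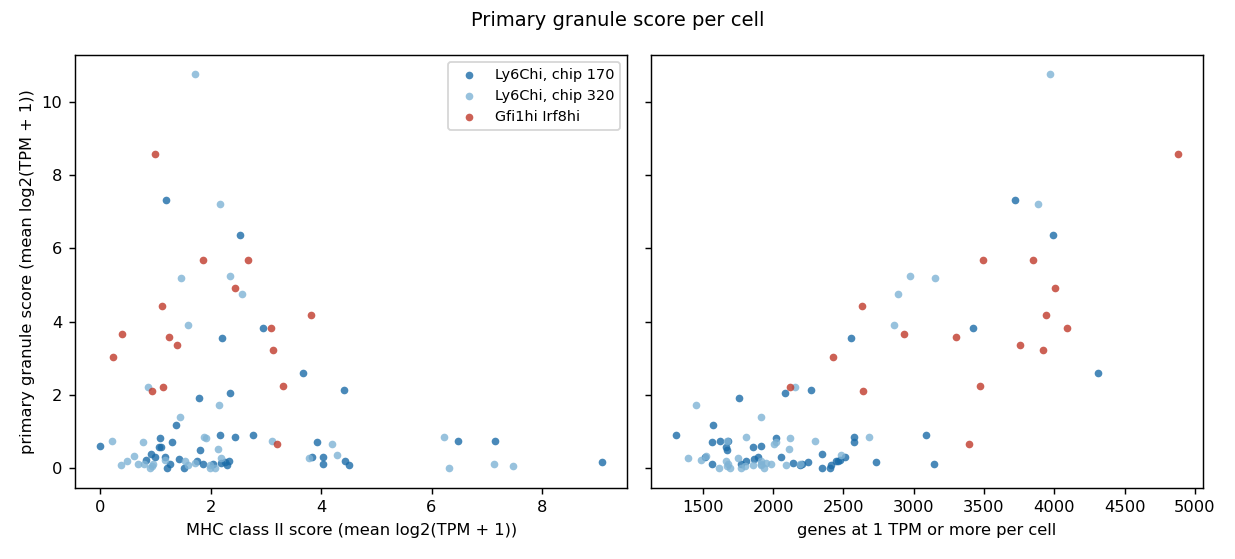
Primary granule score of each cell, as mean log2(TPM + 1), against the MHC class II score and against the number of genes at 1 TPM or more, by sort and capture. Across Ly6Chi cells the Spearman correlation was 0.072 with the MHC class II score and 0.338 with the number of genes, or 0.112 on chip 170 and 0.563 on chip 320.

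Genes that rank with the primary granule score across Ly6Chi cells were headed by Arpc5l (mean of chips 0.485), Lsm3 (0.542), Ran (0.477), Gmnn (0.455), Eif5 (0.429), Exosc8 (0.425), Dnmt1 (0.420), Top2b (0.416), Rasgrp2 (0.415) and Cept1 (0.381). The lowest were Ifitm3 (-0.468), Daxx (-0.449), Trf (-0.444), Pydc4 (-0.429), Zfp36 (-0.392) and Wfdc17 (-0.374). In the held-out Gfi1hi Irf8hi cells 8 of the 10 positive genes kept their sign, with a median of 0.216 (random genes 0.143, percentile 75.35), and 2 of the 5 negative genes that varied there. For the MHC class II score the highest were Sorl1 (0.495), Pitpnc1 (0.403), Vrk1 (0.392), Cbfa2t3 (0.387), Apobec3 (0.376), Ybx1 (0.373), Actn4 (0.367), Gna13 (0.347), Sec23ip (0.346) and Rbm7 (0.329). The lowest were Prdx5 (-0.410), Mina (-0.393), Paip2 (-0.354), Cebpb (-0.350), Cdc42ep3 (-0.340) and Gda (-0.330). In held-out cells 5 of 10 and 2 of 6 kept their sign. Neither set stood apart from random genes there, and with Pearson correlation 3 of 16 and 6 of 16 genes were named again.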

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

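All tests in this part were chosen after the values were seen.

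Sex-linked transcripts, which no comparison used, separated the sorts. A Y-linked transcript (Ddx3y, Eif2s3y, Kdm5d or Uty) reached 1 TPM in 13 of 16 Gfi1hi Irf8hi cells (81.2%, exact 95% interval 54.4% to 96.0%) and in 0 of 80 Ly6Chi cells, where 3 counts of the total allow up to 3.75%. Xist, the transcript of the inactive X chromosome, reached 1 TPM in 44 of 80 Ly6Chi cells (55%, 43.5% to 66.2%) and in 1 of 16 Gfi1hi Irf8hi cells. Loss of detection is argued against for Xist, since the median number of genes was 3480 in Gfi1hi Irf8hi cells and 2019.5 in Ly6Chi cells. In cells matched on gene number a Y-linked transcript was found in 83.3% of 12 Gfi1hi Irf8hi cells (51.6% to 97.9%) and 0 of 12 Ly6Chi cells. The intervals lay apart at each of 6 matching limits. The shares in all cells nearly fixed this outcome, since 0 of 80 Ly6Chi cells leaves 0 in any subset. It shows only that Ly6Chi cells with as many genes also held none at 1 TPM. By these transcripts most Gfi1hi Irf8hi cells were male, and the Ly6Chi cells with Xist were female. The exceptions were low. In 1 Ly6Chi cell a Y-linked transcript lay above 0 but below 1 TPM. Xist lay above 0 in 3 Gfi1hi Irf8hi cells, and reached 10 TPM in 0 of 16 against 34 of 80 Ly6Chi cells. The labels name no sex and no animals, and what sex did to other genes was not tested.

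Cycle and primary granule transcripts were higher by value in Gfi1hi Irf8hi cells, which also showed more genes per cell. With 12 pairs matched on the number of genes, the G2/M median was 1.15 and stayed above the random lists at each of 6 matching limits, which argues against gene number as the whole reason. The primary granule median was -1.16, inside the random lists at all 6 limits, from -1.34 to -0.49. Whether gene number accounts for this cannot be told by matching, because both rose together across Ly6Chi cells (Spearman 0.338, 0.112 on chip 170, 0.563 on chip 320). The highest granule scores there, 10.75, 7.32 and 7.20, lay in cells with 3970, 3718 and 3887 genes. Matching also left out 4 Gfi1hi Irf8hi cells, among them those with the highest granule scores of that sort (8.58, 5.68 and 5.68). It kept the shallow cells and those of low ribosomal protein score, and gave a ribosomal protein median of -1.79. Without shallow cells the granule median was 2.53. Cells that divide may also hold more kinds of RNA. Progenitors in the sort stay open: Kit or Cd34 reached 1 TPM in 25% of Gfi1hi Irf8hi cells (7.27% to 52.4%), and Kit in 1 and Cd34 in 0 of 80 Ly6Chi cells, but both lie near the floor, and of the other progenitor genes Myb did so in 11 of 16 against 5 of 80 and Sox4 in 2 of 16 against 0 of 80, but Flt3 in 1 of 16 against 12 of 80 and Myc in 0 of 16 against 6 of 80. Date, mouse strain and the sex of the animals stay open as causes too.

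Interferon response transcripts were lower by value in Gfi1hi Irf8hi cells. In matched cells the median of the 16 or 17 members above 0 there lay below the random lists at 5 of 6 limits, as with -0.64 within 300 genes (percentile 0.05) and -0.54 with every cell matched (0.02), but within 100 genes it was -0.33, inside them (2.66), so gene number is not excluded. A linear fit over the Ly6Chi cells on the primary granule, S and G2/M scores, read at the scores of the Gfi1hi Irf8hi cells, gave 44.5% of the difference in the interferon score, or 35.5% to 58.6% with 1 cell left out at a time. For 6 of the lowest genes, which the interferon list does not hold, it gave from 17.96% for Cd68 and 28.6% for Ifitm3 to 73.5% for Wfdc17. The 44.5% lay between the limits set for and against this explanation, so whether a dividing state accounts for part cannot be told. Maturity was not measured by the fit. Date, capture and sex of the animals, and mouse strain if it differed, cannot be told apart from the sort.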

How the results depend on the processing

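The matching of cells and the exclusion of shallow or haemoglobin-holding cells were chosen after seeing the data. No paired analysis was possible because the results come from no test and cell numbers pair nothing. Of the values that answer a comparison, 125 moved by no more than the difference between the 2 chips, or stayed in the exact interval of a share, 65 moved by more and 2 reversed. Of the values of single genes and other lists, 897 stayed, 609 moved and 22 reversed. A change of sign counted as a reversal only for lists outside the random lists, for genes whose difference exceeded 1 and that of the chips, and for correlations of genes named by them. Of the values that did not meet this, 8 and 43 changed sign. The 2 filters on cells fixed before the data were examined removed no cell and so say nothing about stability. Each of them makes up 15 of the 125 values and 122 of the 897. Taking 1 chip alone could hardly move a value either. The yardstick was the difference between the chips, and the main value lay between them or close to that. Such settings make up 7 and 7 of the 125 values for correlations, and 8 and 7 for sort differences. Read depth is unknown, so what it limits could not be measured, and shares of cells depend on the detection threshold, as for Mpo in Ly6Chi cells with 58.8% above 0 and 12.5% at 10 TPM.

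The S and G2/M phase medians stayed above 0 under every alternative run. In cells matched on the number of genes, the list medians were -1.16 for primary granule, -0.73 for secondary and tertiary granule, 0.90 for S phase and 1.15 for G2/M phase, and the differences were -1.45 for Irf8 and -0.40 for Gfi1. Glycolysis turned to -0.998, the respiratory chain to -1.71, Serpinb1a to -4.97, Ly6c2 to -1.11, Ly6c1 to -1.39 and Emr1 to 0.24, none of them counted as reversed. Interferon response was at -0.33, sort markers at -0.77, ribosomal protein at -1.79 and Ly6Clo monocyte at 0. Other genes reversed there: Aurka (-0.30), Ccnb1 (-0.38), Ccnb2 (-1.34), Ccne2 (-0.22), Cdk1 (-1.43), Gins2 (-0.68), Hmmr (-0.76), Mcm2 (-0.38), Mcm4 (-0.88), Rrm1 (-0.35), Ctsg (-3.53), Ms4a3 (-1.16), Spn (-1.16), Csf1r (0.14), Ear2 (0.49), Id2 (0.40), Ifit3 (0.23) and Rtp4 (0.0858). The 24 genes named between the sorts kept their direction under all 12 alternatives for single genes. Of these alternatives, 2 removed no cell and 2 took 1 chip alone, where the rule for naming these genes already required the same sign. The genes were also chosen for large differences in these same cells, so their kept direction says little about stability. Of the genes' values, 132 moved by more than the chip difference and 156 did not. In matched cells Stmn1 was at 0.16 and Hmgn2 at 1.18.

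With the ratio of mean values, which a few high cells can set, the differences were 0.50 for Irf8 and -0.42 for Gfi1, and the medians 1.65 for primary granule, -2.09 for secondary and tertiary granule, -1.40 for MHC class II, -2.63 for dendritic cell, 1.80 for S phase and 1.74 for G2/M phase. Hmmr turned to -0.19 and the ribosomal protein median to 0.14, while sort markers were at -2.41 and Ly6Clo monocyte at -4.41. With medians over cells, Irf8 differed by 3.66, primary granule by 1.09 and S phase by 4.99, while secondary and tertiary granule, MHC class II and dendritic cell were at 0, sort markers at -0.27 and ribosomal protein at 0.16. A pseudocount of 0.1 gave 3.56 for primary granule, -0.86 for MHC class II, -0.23 for dendritic cell, 4.48 for S phase and 4.57 for G2/M phase. A pseudocount of 10 gave 1.36, -0.38, -0.087, 1.85 and 1.72 for the same lists. Rescaling gave 2.68 for primary granule. Without the 3 haemoglobin-holding cells, primary granule was 2.90 and MHC class II -0.20. With members in at least 10% of cells, primary granule was 3.96, MHC class II -0.85 and dendritic cell -0.765. Without shallow cells, MHC class II was -0.052, dendritic cell -0.10, S phase 3.97, sort markers -0.51 and ribosomal protein 0.42. Without chip 320, dendritic cell was -0.19.

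For co-expression, leaving out cells with Mki67, Top2a or Cdk1 gave 0.120 for primary granule, 0.0861 for secondary and tertiary granule, 0.0652 for S phase and 0.0550 for G2/M phase. Pearson correlation gave 0.162 for secondary and tertiary granule, 0.275 for MHC class II and 0.474 for G2/M phase. Secondary and tertiary granule had 0.106 with partial correlation, 0.0423 with members in at least 30% of cells and 0.0579 in Gfi1hi Irf8hi cells. MHC class II had 0.110 with members in at least 30% of cells and 0.215 in Gfi1hi Irf8hi cells, where G2/M phase had 0.170. Dendritic cell had -0.310 with members in at least 30% of cells. The correlation of the primary granule and MHC class II scores was -0.0651 with Pearson, 0.0379 with partial correlation, 0.0555 with members in at least 30% of cells, -0.0849 without the cycling cells, -0.0176 in Gfi1hi Irf8hi cells and 0.0468 without shallow cells. Of the 16 genes named for the primary granule score, 3 were named with Pearson and 8 with partial correlation, and for MHC class II 6 with Pearson. At 10 TPM the Ly6Chi shares were 21.2% for Elane, 12.5% for Mpo and 20% for Prtn3. The cause of these moves was not tested.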

Other observations

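Genes outside the compared lists also set the sorts apart. Those named in this part were chosen from the fixed lists after their values were seen. Klf2, a transcription factor of quiescence and migration, had means of 7.25 ± 3.05 in Gfi1hi Irf8hi and 3.36 ± 3.45 in Ly6Chi cells, and Myb, a factor of progenitors, 3.88 ± 2.86 and 0.32 ± 1.31. Myb reached 1 TPM in 11 of 16 and 5 of 80 cells. The 19 myeloid transcription factors measured had a median difference of 0.45 (random lists 0.58), or 0.19 against chip 170 and 0.57 against chip 320, and the 9 progenitor genes 0.10 (random lists 0.13). Glycolysis genes had a median of 1.11 (percentile 92.2), with Pgk1 at 4.06 and Pgam1 at 3.32, and respiratory chain genes 0.78 (percentile 68.6). In cells matched on the number of genes both turned, to -0.998 and -1.71. Ly6Clo monocyte genes had a median of -0.19 (percentile 0.03), with Gngt2 at -3.56 and Emr4 at -2.01, while Itgal was higher by 2.02. The list's median was 0 in matched cells and with medians over cells, and -4.41 with the ratio of means. Ribosomal protein genes had a median of -0.67, whose direction turned with the ratio of means, with medians over cells and without shallow cells. In matched cells the ribosomal protein median was lower still, at -1.79.

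The immediate early genes, which respond to handling as well as to signals, had a median of 0.37 (random lists 0.40). Fosb differed by 3.91, Ier2 by 2.80 and Atf3 by -2.71. Within the Ly6Chi sort they had a mean pairwise correlation of 0.152 and interferon response genes 0.160, both at percentile 100. The inflammatory response list had a median difference of -0.07, or -0.15 against chip 170 and 0.0093 against chip 320. The tissue macrophage list had -0.27, or -0.49 and -0.059, and the chips differed by 0.42 (percentile 100). Lists of other cell types had medians of 0.60 for erythroid, above its random lists (percentile 99.82), and, inside theirs, 0.31 for basophil, mast cell and eosinophil, 0.21 for B cell, 0.07 for plasmacytoid dendritic cell and -0.06 for T and NK cell, which was -0.13 against chip 170 and 0.08 against chip 320. Megakaryocyte and stromal lists had 1 and 2 members above 0 and were given no median.

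Across Ly6Chi cells, the primary granule and S phase scores had a Spearman correlation of 0.218 (random pairs 0.328, percentile 16.11), with 0.120 on chip 170, 0.317 on chip 320 and 0.102 without the 2 farthest cells. The Pearson correlation was 0.784. The primary granule score had a Spearman correlation of -0.159 with the Ly6Clo monocyte score (random pairs 0.237, percentile 0.04), with -0.255 on chip 170 and -0.063 on chip 320. The G2/M score had -0.228 with it (percentile 0.00). In Gfi1hi Irf8hi cells these values were 0.316 and 0.071. Of 306820 values above 0, 24.8% lay below 1 TPM, 20.1% from 1 to below 10 TPM and 55.2% at 10 TPM or more. The only cell with Gfi1 above 0, cell 54 of chip 320, also had the highest primary granule score of all cells, at 10.75.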
